A study of Homo sapiens with 3 samples.

How the data were processed

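Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map sites occupied by TEAD1, a DNA-binding partner of the co-activators YAP1 and WWTR1, in primary human epidermal keratinocytes, the main cell type of the epidermis. The samples were 2 libraries from a TEAD1 antibody and 1 input library made without antibody. Per the labels' protocols, cells were fixed with 2 mM DSG, a protein-to-protein crosslinker, and 1% formaldehyde. The labels name an RNA library kit, although they give the sequenced molecule as genomic DNA.

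The authors deposited 1 peak list for the whole series, with a chromosome, start, end and score per peak and no header. BWA 0.7.13, Picard 2.10.6, MACS2 2.1.1, bedtools and the build hg19 are named in the submitters' processing notes, without a role or an order. Whether and how each of the 3 libraries entered the list, and what the score measures, is not given in the sources used here. The deposited score is a whole number from 540 to 1000 and is the authors' own value for each peak. It was used only to describe and split peaks within this list. The list holds no value per library, no read count and no peak summit. The depth behind each peak is therefore unknown here, and neither an error between replicates nor a comparison of ChIP with input could be computed. All p-values describe positions and peaks within this list, not variation between cultures.

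No hg19 sequence or gene annotation was used here. For that reason the results planned before the data were examined on promoters, introns and exons, on sequence motifs, on gene lists near peaks, and on peak strength by motif or location were not run. The rule for naming genes was also fixed then. It asked for TEAD1, TEAD2, TEAD3, TEAD4, YAP1, WWTR1, CTGF, CYR61, ANKRD1, AMOTL2, LATS2 and AJUBA, for the members of each list with most peaks near their starts, for the genes nearest to the highest peaks, and for the genes with most peaks around them. It could not be applied, so no peak is assigned to a gene. The RefSeq gene table at hand is on GRCh38, and the results reported here use it only for the number of protein-coding genes on each chromosome, which needs no position. Tests of the gene lists, of the fixed genes and of gene density at the level of bands, which joined GRCh38 gene positions to hg19 peaks by band name, were run and then withdrawn after their results had been seen. The edges of some bands differ between the builds, so genes could be placed in the wrong stretch; none of those results is reported here.

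Peaks were assigned by their centre to the hg19 cytogenetic bands shipped with the R package circlize 0.4.16 (R 4.3.3). The build was checked by length: 0 peaks ran past the end of an hg19 chromosome, while 82 peaks on 11 chromosomes lay past the chromosome ends of GRCh38. Centromeric, variable and stalk bands were set aside with their 102 peaks, which left 746 autosomal bands with a median length of 3.32 Mb. Bands of at least 1 Mb were ranked by density. The 15 densest bands, the 9 sparsest, the autosomal clusters of at least 9 peaks and the 4 widest autosomal peaks are named, all chosen by rank after their values were seen. The genes that 3 bands are described by are general background on human chromosome maps, chosen after the ranks were seen, and not a result.

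Spacing between peak centres was compared with 1000 random placements, within the same chromosome, of the 24755 peaks outside the bands set aside. The plan was to place peaks outside assembly gaps; no table of gaps was used here, so gaps inside the other bands stayed open to random placement, which lowers the random shares by an unknown amount. The share of peaks in Giemsa-negative bands was compared with 1000 rotations of each chromosome's peaks, which keep their spacing. Clusters were runs of peaks with gaps of at most 12.5 kb and were set beside 200 placements. Widths, correlations and ceiling shares were tested with 100000 permutations. All permutation tests were two-sided. Describing the peaks and setting the distances between neighbours beside random placements was planned before the data were examined. The 10 kb distance, the other tests and every alternative reported were chosen after the peak list had been seen. Alternatives kept only peaks at the score ceiling, only autosomes, peaks merged when less than 1 kb apart, or all but the widest 5%, or changed the neighbour distance, the random placement or the chromosome length used. Intervals on peaks per Mb are exact Poisson 95% intervals. They cover counting error only and are too narrow where peaks cluster. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

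The placement and rotation tests were tested on simulated data. With 10% of uniformly placed peaks moved next to a neighbour, 31.2% had a neighbour within 10 kb against 16.7% at random (permutation p = 0.0099, the smallest that its draws allowed), and uniform peaks gave a permutation p of 0.97. Moving peaks into Giemsa-negative bands raised their share from 46.1% to 56.1% (permutation p = 0.0050), against a permutation p of 0.98 for uniform peaks. The simulations had no assembly gaps and were not repeated, and uniform peaks were drawn as the random placements are. The peaks moved into Giemsa-negative bands were not clustered. The error rate of the tests on clustered peaks or around gaps is therefore not shown by them. The 392 peaks on the sex chromosomes entered only results over all chromosomes.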

Results

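TEAD1 occupancy was mapped by ChIP-seq in primary human keratinocytes to ask where this factor, studied together with TEAD3 for a part in epidermal proliferation, sits on the genome. The series comprised 2 TEAD1 ChIP libraries and 1 input library, and the data were 1 peak list; how each library entered it is not given in the sources used here. The list held 24857 separate intervals, of which 0 overlapped, and together they covered 15.3 Mb of hg19. The 24465 autosomal peaks covered 0.526% of the autosomes, at a mean of 8.49 peaks per Mb of full chromosome length. Peaks were narrow, with a median width of 557 bp, quartiles of 412 and 753 bp, and a range from 170 to 3873 bp. The list gives no value per library, so no replicate error could be attached to a peak.

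TEAD1 peaks were found on all 22 autosomes, and most sparsely on chromosome 13. Which autosome was densest depended on the length used. Over full chromosome length, chromosome 17 carried 11.8 peaks per Mb (95% Poisson interval 11.1 to 12.6, 957 peaks), which was 2.07 times the 5.69 per Mb of chromosome 13 (5.26 to 6.14, 655 peaks), and chromosomes 19 and 20 followed, each with 10.2. With centromeric, variable and stalk bands left out, chromosomes 19, 22 and 17 could not be told apart, with 12.4 (11.4 to 13.5), 12.3 (11.1 to 13.5) and 12.3 (11.5 to 13.1). Chromosome 13 stayed lowest with 6.85 (6.33 to 7.39). Chromosome 4 was next with 7.43 (7.04 to 7.83), and these intervals overlap. Chromosome 21 rose from 7.06 to 10.1. Relative to protein-coding genes the order was different. Chromosome 18, which is gene-poor, had 233 peaks per 100 genes, and chromosome 19, the most gene-dense autosome, had 41.7, a 5.60-fold difference.

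Peak density rose with gene density across the 22 autosomes. Pearson's r was 0.64 (permutation p = 0.0018) and Spearman's rho was 0.62 (permutation p = 0.0024). Both had an adjusted p of 0.0024 over these 2 measures of the same relation. The adjustment covers no other test reported here. Without chromosomes 17 and 19, the farthest from the median gene density, r was 0.61 and rho 0.50 (permutation p = 0.0044 and 0.025). With centromeric, variable and stalk bands left out of the length and the peaks, r was 0.76 and rho 0.86 (permutation p = 1e-05 for each). Gene counts stayed those of the whole chromosome there, so genes in the bands left out were still counted. Both densities share the same length as divisor, which can by itself produce a correlation. The permutations shuffled the finished densities and do not remove that.

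**Figure D1:**
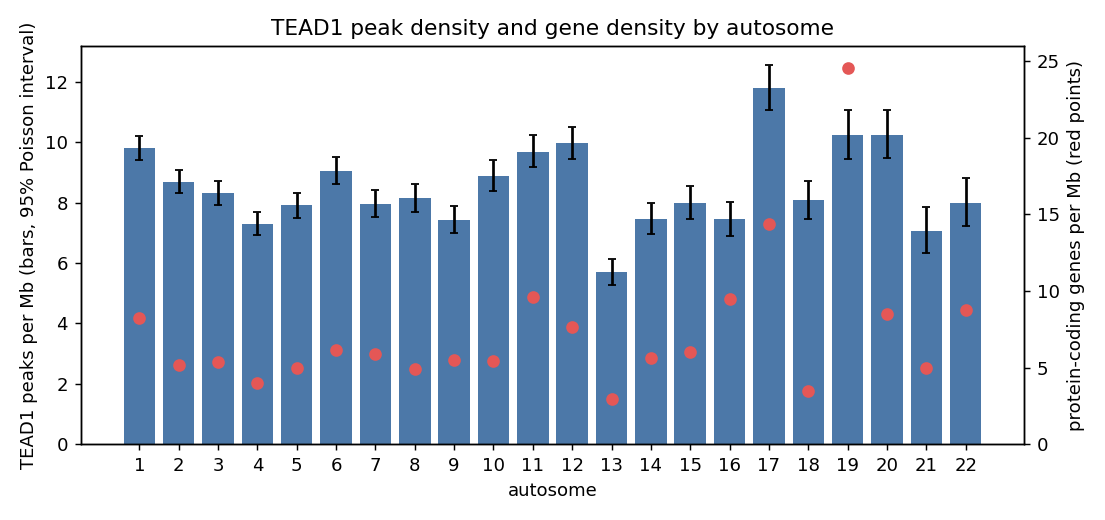
TEAD1 peaks per Mb of full length for each autosome (blue bars, left axis, with 95% Poisson intervals) and protein-coding genes per Mb (red points, right axis). Over full length, which includes the bands set aside elsewhere, chromosome 17 has the highest value (11.8 per Mb) and chromosome 13 the lowest (5.69 per Mb), while chromosome 19 has the most genes per Mb (24.5) with 10.2 peaks per Mb.

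Within chromosomes, peak density varied between cytogenetic bands, with a median of 9.38 peaks per Mb over 746 bands and quartiles of 6.09 and 12.6. Band 17q21.2 ranked first of the 709 bands of at least 1 Mb, with 30.8 peaks per Mb (24.3 to 38.5, 77 peaks), 3.28 times the median band. It was followed by 19q13.32 with 26.8 (21.1 to 33.6, 75 peaks), 6p21.33 with 25.9 (18.8 to 34.7, 44 peaks), 11p15.3 with 25.5 (51 peaks), 2p23.2 with 25.2 (53 peaks) and 12q13.13 with 24.4 (19.4 to 30.3, 83 peaks). Next were 11q13.1 with 23.2 (58 peaks), 6p25.2 with 22.1 (42 peaks), 21q22.12 with 44 peaks in 2 Mb, and 8q24.21 with 21.7 (91 peaks). The last 5 of the 15 densest, from 21.3 to 20.4 peaks per Mb, were 1q21.3 (100 peaks), 7q32.2, 22q12.2, 1q42.3 and 14q24.1.

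As background, 3 of these 15 bands are known for genes of the epidermis: 17q21.2 and 12q13.13 for the keratin gene clusters, and 1q21.3 for the epidermal differentiation complex. They were singled out after the ranks were seen, and no test is given of whether epidermal genes lie in dense bands more often than other genes. All of these bands span megabases and hold many other genes, and which gene a peak lies in or near was not analysed here.

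The sparsest bands held almost no peaks. Of the bands of at least 1 Mb, 5 had 0 peaks: 9p11.2, 9p12 and 11p11.12, which lie near centromeres, and 12p12.2 and 22q13.32. The upper Poisson bound allowed them from 0.997 peaks per Mb (9p11.2) to 3.69 (22q13.32). Band 13q21.1, in the darkest Giemsa class, held 1 peak in 4.3 Mb. Band 9q13 held 1 peak in 2.8 Mb, and the adjacent bands 15q11.2 and 15q12 held 2 and 1. Assembly gaps inside bands were not subtracted, so a low value here is not evidence of absent binding.

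Peaks were more frequent in lightly stained bands, which tend to be gene-rich. Giemsa-negative bands held 53.1% of peaks against 46.0% ± 0.78 (SD) in rotated positions (permutation p = 0.001, the smallest possible). On the autosomes their density was 10.6 peaks per Mb (10.4 to 10.8), against 5.47 (5.26 to 5.69) in the darkest class, a ratio of 1.93. The fall was not even over the classes: the lightest grey bands carried 11.7 peaks per Mb (11.2 to 12.2), and the next carried 9.06 and 7.76.

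**Figure D2:**
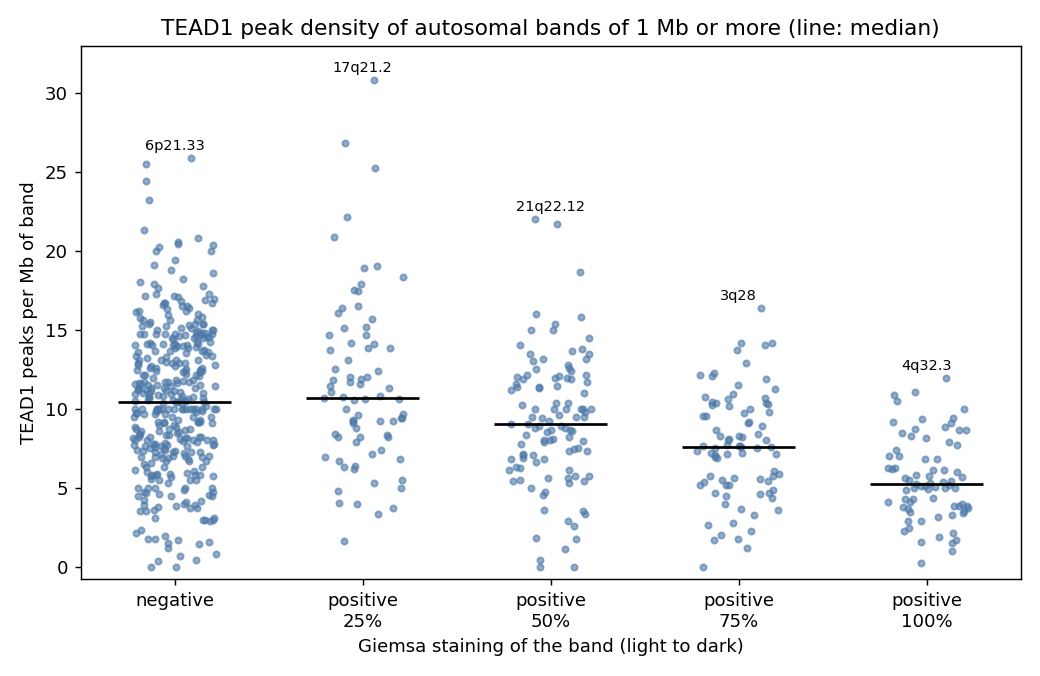
Each point is an autosomal band of at least 1 Mb, placed by its Giemsa class (x axis, light to dark) and its TEAD1 peaks per Mb (y axis), with the median of each class as a line and the densest band of each class named. Band 17q21.2 is the highest at 30.8 peaks per Mb, and 3q28 leads its darker class at 16.4.

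TEAD1 peaks lay close together. Of the 24755 peaks outside centromeric, variable and stalk bands, 38.9% had another peak centre within 10 kb, against 16.8% ± 0.32 (SD) in random placements on the same chromosome (permutation p = 0.001, the smallest possible). The median distance to the nearest peak was 16494 bp, against 38033 bp at random. Placement inside each peak's own band gave 19.4% ± 0.32, and moving each peak by 20 to 100 kb gave 27.4% ± 0.33, both below the observed share (permutation p = 0.001 for each).

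**Figure D3:**
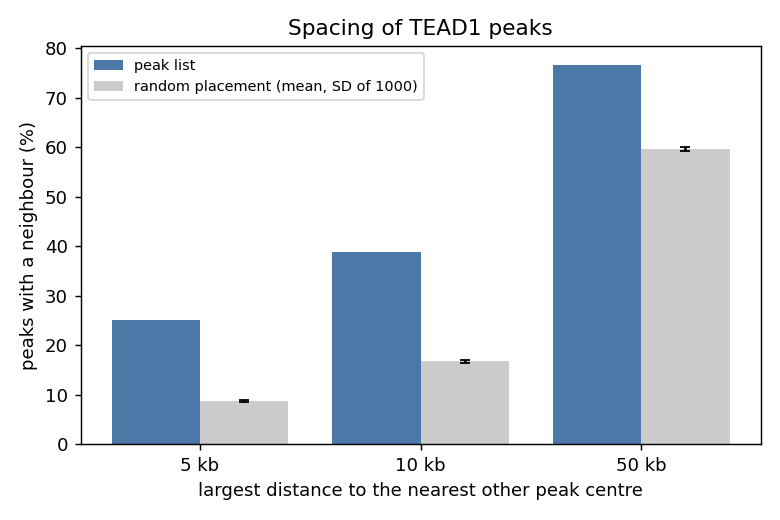
Share of TEAD1 peaks with another peak centre within 5, 10 or 50 kb (blue) and the mean of 1000 random placements on the same chromosome with its SD (grey). The observed shares of 25.1%, 38.9% and 76.7% lie above the random 8.79%, 16.8% and 59.7%.

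Joined across gaps of up to 12.5 kb, peaks formed 174 clusters of 5 or more, which held 4.07% of the peaks. Random placement on the same chromosome gave 4.08 ± 2.03 (SD) such clusters, and placement within the same band gave a highest count of 23 in 200 placements. The largest cluster held 11 peaks. Placement on the same chromosome gave a largest cluster of 5.41 peaks on average and at most 7. Placement within the same band gave 6.85 ± 1.15 (SD) and at most 11 in 200 placements, so its highest value equalled the observed size. That placement keeps each band's own peak count. Short bands with many peaks include 19p13.13 (10 peaks in 0.1 Mb), 15q22.33 (11 in 0.2 Mb) and 19q13.13 (12 in 0.4 Mb). In which bands the placement within the same band reached 11 was not analysed here. The autosomal clusters of 11 peaks lay in 15q22.2 (chromosome 15, 60663244 to 60714187) and in 19q13.2 (chromosome 19, 39129099 to 39184664). Clusters of 10 peaks lay in 10q23.33 (chromosome 10, 95195882 to 95235995), 3p14.3 (chromosome 3, 57955476 to 58007458) and 6p24.3 (chromosome 6, 10400497 to 10464261). In the cluster of 10q23.33, 9 of the 10 peaks were at the score ceiling. Clusters of 9 lay in 19p13.13 (chromosome 19, 13944463 to 13973200), 1q32.2 (chromosome 1, 209530215 to 209563213) and 10p11.21 (chromosome 10, 34987949 to 35033117). All coordinates are on hg19, and whether these intervals are exonic, intronic or intergenic was not analysed here.

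Peaks at the top of the score range were wider. The score was at its ceiling of 1000 in 15059 peaks (60.6%), so the top of the list could not be ranked by it. Ceiling peaks had a median width of 635 bp and the other 9798 peaks 450 bp (difference 185 bp, permutation p = 1e-05, the smallest possible). Below the ceiling, score and width were weakly related across peaks, which are not independent replicates (Spearman rho = 0.17, permutation p = 1e-05). The widest autosomal peak, of 3873 bp, lay in 8p11.23 (chromosome 8, 37000311 to 37004183), and the next, of 3699 bp, in 1p36.13 (chromosome 1, 16470124 to 16473822). These were followed by peaks of 3044 bp in 4q35.2 (chromosome 4, 187647607 to 187650650) and 2997 bp in 12q13.13 (chromosome 12, 52914171 to 52917167). Peaks with a neighbour within 10 kb were at the ceiling slightly more often (62.4% of 9625) than those without (59.5% of 15130), a difference of 2.94 percentage points (permutation within chromosomes, p = 2e-05). That permutation treats peaks as independent, but neighbours come in pairs and clusters, so its p may be too small.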

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

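All alternatives in this part were chosen after the peak list had been seen. Those planned beforehand concerned gene parts, motifs, gene lists near peaks and peak strength by motif, and none was run, since no hg19 sequence or annotation was used here. No paired analysis was possible because the 1 list holds no value per library, and leaving out a replicate was not run for the same reason. Keeping only ceiling peaks left 15059 of the 24857 peaks by its own construction. The other subsets held 23562 to 24465, so they largely repeat the full list and their agreement with it is weak support. The excess of near neighbours, the Giemsa-negative share and the correlation with gene density across autosomes kept their direction under each alternative run for them. So did the width difference and the higher ceiling share of neighbouring peaks. Each kept a permutation p below 0.05. The share with a neighbour within 10 kb ranged from 28.8% (ceiling peaks only) to 39.2% (autosomes only). A smaller set has fewer neighbours at random too, 10.6% for ceiling peaks only against 16.8% for the full list. Relative to random, the share was 2.73-fold for ceiling peaks only, 2.32-fold for the full list, 2.31-fold for autosomes only and 2.03-fold for merged peaks. The Giemsa-negative share ranged from 52.9% to 53.3%. Spearman's rho ranged from 0.50 (without chromosomes 17 and 19) to 0.86 (centromeric, variable and stalk bands left out of length and peaks, but not of gene counts). The difference in ceiling share ranged from 2.1 percentage points (neighbour within 5 kb, 62.2% against 60.1%, permutation p = 0.0059) to 3.47 (within 50 kb). These permutations also treat peaks as independent. Merged peaks took the highest score of their members, which can itself raise a ceiling share. The depth per library was unknown, so a region without a peak cannot be read as unbound.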

Other observations

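The tests on the score floor and on the order of lines were chosen after those values had been seen, and how the test on dark bands is read was changed after its result was seen. The bounds of the tests on merged peaks and on placement inside bands were set before their results, on a peak list already examined.

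Centromeric bands of the autosomes held few peaks, 58 in 98.2 Mb (0.591 per Mb, 95% Poisson interval 0.448 to 0.764). Of these, 60.3% were at the score ceiling, against 60.6% of all peaks. Variable bands held 43 peaks, of which 21 (48.8%) were at the ceiling, too few to read a difference in ceiling share. Their density was 0.439 per Mb (0.318 to 0.591). These lengths include stretches without assembled sequence, where no peak can be called, and how much of each band that is was not analysed here, so the low densities say nothing on binding. Stalk bands are left out for the same reason.

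The close spacing of peaks was not fully accounted for by either technical explanation tested. If single enriched stretches had been called as several peaks less than 1 kb apart, merging such peaks should have removed the excess. After merging, 32.3% of peaks still had a neighbour within 10 kb, against 16.0% ± 0.32 (SD) at random. Stretches split by wider gaps are not joined by that merging, so they stay open. Uneven density between bands was also too small, since 38.9% was observed against 19.4% ± 0.32 with placement inside each band. Density at a finer scale goes further: moving each peak by 20 to 100 kb gave 27.4% ± 0.33, well above the 16.8% of placement on the chromosome but below the observed share. Uneven mappability or copy number at that scale stays open, as may groups of regulatory elements around particular genes; neither was tested.

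Why Giemsa-negative bands held more peaks stays open. Weaker signal in dark bands could not be judged by the test run. The share of ceiling peaks in the darkest bands minus that in Giemsa-negative bands was -1.45 percentage points, against -0.51 ± 1.04 (SD) in permutations. The value lies within that spread, and sites too weak to be called do not enter it. The bound set beforehand would have counted a value inside the permutation spread against weaker signal as the explanation. That bound was wrong, since the score is capped in 60.6% of peaks and a small difference within the spread excludes nothing. Gene content stays open too: a test of it that used GRCh38 gene positions was run and withdrawn after its result was seen, because band edges differ between the builds, and no hg19 annotation was used here.

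No peak scored under 540, and 15059 shared the score 1000. A candidate explanation is that the score is a scaled irreproducible discovery rate, a measure of how well replicate peak ranks agree, kept at 0.05: the usual scaling of that threshold gives 540, the lowest score found. If so, the list may hold peaks found in both ChIP libraries, but no label states that or what was compared to obtain the score.

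The order of lines in the list carried information that the capped score did not. Among ceiling peaks, width fell along the list (Spearman rho = -0.36 across peaks, permutation p = 1e-05). In 10 equal parts of the list, the median width went from 806.5 bp in part 1 to 400 bp in part 10, and the share at the ceiling from 100% in part 1 to 1.25% in part 9 and 7.81% in part 10. With 50 equal parts, part 50 had 36.8% of peaks at the ceiling and a median width of 271 bp, against 1.01% and 443 bp in part 49. What the order stands for is not given in the sources used here.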
